A study of Homo sapiens with 6 samples.

How the data were processed

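The data are gene counts from 6 RNA-seq libraries of Kasumi-1 cells, 3 control and 3 with a PHF19 hairpin. Per the labels' protocols, cells were transduced with lentivirus, selected with puromycin at 2 µg/ml from 48 h after transduction for at least 24 h, and lysed in TRIzol, and libraries were made from total RNA with the KAPA Hyper Prep kit. Groups and replicate numbers were taken from the sample titles. Per the submitters' processing notes, HISAT2 2.1.0, HTSeq 0.11.2 and the genome build hg38 were used. The gene annotation, the strand setting of the counting and the order of steps are not given in the sources used here. The hairpin sequence is not given there either, so matches to other transcripts were not searched.

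The authors deposited a table of whole-number counts per gene symbol with 26410 rows, not normalized, of which 6991 have no count in any library. In it 28 gene names had been turned into dates, holding 0.19% of all counts. These rows were kept in the tests and are not named, because a date can stand for more than 1 gene. No mitochondrially encoded gene is in the count table, so that list was not tested. The authors also deposited a table of their own comparison, with the mean normalized signal per gene (baseMean), log2 fold changes and their errors, and p-values with adjusted p-values. Of the 5740 genes in the authors' deposited table, the largest adjusted p is 0.00993, the smallest baseMean is 10.1 and the smallest absolute log2 fold change is 0.32, so the table appears to have been filtered. The tool behind the authors' deposited table is not given in the sources used here. The values of the authors' deposited table were compared with a DESeq2 fit of all rows with a count. The median ratio of baseMean was 1, the median absolute difference of log2 fold change was 0.018, and the median difference of the p-value was 0.94%. The authors' deposited table holds 6 gene names that are absent from the count table, all of kinds that spreadsheets turn into dates.

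The counts as deposited were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which left 13014, libraries were scaled by TMM, and group was the only term in the quasi-likelihood F test (glmQLFit and glmQLFTest, robust). P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The standard error of a log2 fold change is the change divided by the square root of its F value. The biological coefficient of variation was 0.0915. CPM are TMM scaled and were computed here. Gene lists, 36 in number, were fixed with their members before the data were examined, as were the tests, the alternatives and the rule for named genes. Lists with at least 5 tested members (35) were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists, and also with camera with an estimated correlation and with fry. Fry tests a list on its own and does not compare it with other genes. List members called measured are those that passed the filter, and other listed members may still hold some counts.

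The text names PHF19, the 12 largest rises and the 12 largest falls, PRC2 subunits, up to 4 members of a described list with the smallest adjusted p, and the 3 genes with the most counts. The largest changes were taken among genes past the threshold with a mean of at least 5 CPM and no overlap between groups, passing over genes with clone-based names, pseudogenes and Y-linked genes. Some results that the rule covers are not reported here. Genes named outside this rule are said to be so where they appear, except that LYZ, ELANE and MPO also appear under a second list they belong to. Genes such as HSPA8, EIF5A and those of ribosomal proteins have near-identical processed copies in the genome, so their values depend on how the authors' counting treated shared reads.

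The 6 libraries hold 14229878 to 16615143 counts. At this depth 3 counts, the limit that a count of 0 allows, correspond to 0.181 to 0.211 CPM. Where a group held few counts, a ratio is given with an exact (Clopper-Pearson) interval, which covers counting error only. Each pair of replicates differed by more than sampling noise (chi-square over degrees of freedom 4.78 to 12.4), so each library was kept as a replicate. Gene positions, exon lengths and GC content came from GENCODE 29 (GRCh38), matched by symbol for 23655 rows and 93.8% of tested genes.

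The fit was tested on simulated counts for this comparison with known fold changes (12841 genes run). It recovered 83 of 96 genes changed 2-fold (86.5%) and 62 of 100 genes changed 1.41-fold, with 13 false calls among 158. The list test called 10 of 10 raised lists and 0 of 30 others in the simulation with camera at the preset correlation. Simulated genes varied independently of each other, so this result does not bear on the choice of correlation. Few genes were changed in the simulations, whereas most were called in the data, so scaling under a broad change was not tested. The alternatives were RLE and upper-quartile factors, library totals only, no low-count filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, no robust dispersion, the replicate number as a block, removal of a gene length trend, and each library left out in turn. Removal of a GC content trend, alone or with the length trend, was added after the data were seen.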

Results

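RNA was sequenced from Kasumi-1, a human acute myeloid leukaemia cell line that carries the RUNX1::RUNX1T1 fusion, after lentiviral delivery of a hairpin against PHF19 or of a scrambled control hairpin. PHF19 is an accessory subunit of Polycomb repressive complex 2 (PRC2), which methylates lysine 27 of histone H3. The comparison asked which transcripts differed once PHF19 was silenced. There were 3 control libraries and 3 libraries with the PHF19 hairpin (shPHF19). The treatment label of the control samples reads wild type, whereas the series title and the treatment protocol name a scrambled hairpin. The total counts were 15172183, 15961787 and 14229878 in control replicates 1, 2 and 3, and 14663463, 16615143 and 15383924 in shPHF19 replicates 1, 2 and 3. Genes with at least 1 count numbered 16576 ± 112 (SD, n = 3) in the control libraries and 15886 ± 71.8 (SD, n = 3) in the shPHF19 libraries (exact permutation test, 2-sided, p = 0.1, the smallest that 3 against 3 allows). The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

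PHF19 transcript was lower in each shPHF19 library than in each control library. It stood at 185 ± 16.1 CPM (counts scaled to library size; SD, n = 3) in control cells and at 37.0 ± 4.04 CPM (SD, n = 3) in shPHF19 cells, which is 5.00-fold lower. The log2 fold change was -2.32 (SE 0.0975; edgeR quasi-likelihood test, adjusted p = 3.55e-25). The gene lies on the minus strand of chromosome 9 from 120855652 to 120894896 (GRCh38, GENCODE 29). The control values were 168, 199 and 189 CPM, and the shPHF19 values were 41.1, 36.9 and 33.1 CPM.

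The other PRC2 subunits and partners moved in both directions. Of 11 measured, 4 rose, 3 fell and 4 did not pass the test. Among all 13014 genes tested 60.2% passed, so this count does not set the list apart. Adjusted over the list alone, 4 rose and 4 fell. EZH2, the main methyltransferase of the complex, rose from 107 ± 11.4 to 153 ± 9.98 CPM (log2 fold change 0.52), while its paralog EZH1 fell from 78.5 ± 3.84 to 55.2 ± 1.61 CPM (-0.51; SD, n = 3 throughout). PHF1, a Polycomb-like protein related to PHF19, fell from 45.7 ± 3.10 to 23.5 ± 2.72 CPM (-0.96). The log2 fold changes of RBBP7, RBBP4 and LCOR were 0.30, 0.26 and -0.49. MTF2, the remaining Polycomb-like protein, had a log2 fold change of 0.22 (edgeR adjusted p = 0.0412), a call lost without control replicate 2 (edgeR adjusted p = 0.16), control replicate 3 (0.0626), shPHF19 replicate 2 (0.12) or shPHF19 replicate 3 (0.127). MTF2 also lost its call with the replicate number as a block (0.22, edgeR adjusted p = 0.104) and with upper-quartile factors (0.11, edgeR adjusted p = 0.293). Over all alternatives its adjusted p ran from 1.68e-05 (limma-voom with the GC trend removed) to 0.931 (edgeR, library totals only). With library totals only, RBBP4 (0.05, edgeR adjusted p = 0.564) and RBBP7 (0.09, edgeR adjusted p = 0.32) also lost their calls. RBBP4 lost its call with upper-quartile factors too (0.16, edgeR adjusted p = 0.0896). LCOR was no longer called without control replicate 3 (-0.35, edgeR adjusted p = 0.0554), with the length trend removed (-0.26, limma-voom adjusted p = 0.0848) or with the length and GC trends removed (-0.18, limma-voom adjusted p = 0.156; from 6.63e-05 over the alternatives). SUZ12, EED, JARID2 and AEBP2 did not pass, with log2 fold changes of -0.20, 0.04, -0.05 and -0.20. SUZ12 was called without control replicate 2 (-0.30, edgeR adjusted p = 0.00828) or without shPHF19 replicate 3 (-0.30, edgeR adjusted p = 0.00469; 0.000475 to 0.831 over the alternatives). SUZ12 was also called with library totals only (-0.41, edgeR adjusted p = 0.000475) and with upper-quartile factors (-0.31, edgeR adjusted p = 0.00396). With the filter of 1 CPM in 3 libraries it was called too (-0.21, edgeR adjusted p = 0.0465). Some scalings and trends brought the others past the threshold. AEBP2 was called with library totals only (-0.41, edgeR adjusted p = 0.00436) and with upper-quartile factors (-0.31, edgeR adjusted p = 0.0293; up to 0.903 over the alternatives), and JARID2 with library totals only (-0.26, edgeR adjusted p = 0.00644; up to 0.865). EED was called with the GC trend removed (0.34, limma-voom adjusted p = 0.0055) and with the length and GC trends removed (0.36, limma-voom adjusted p = 0.00386; up to 0.988 over the alternatives). As a set the list was not called (camera adjusted p = 0.913).

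**Figure D1:**
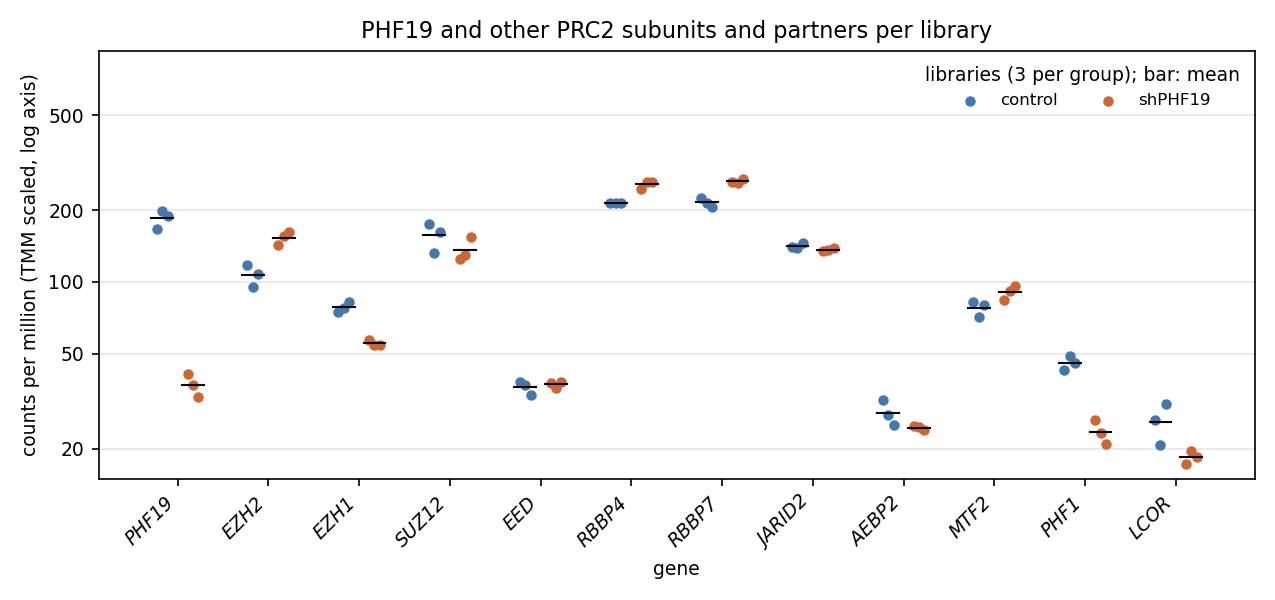
CPM of PHF19 and of 11 other PRC2 subunits and partners on a log axis, with 1 point per library (3 control, 3 shPHF19) and a bar at the mean of each group. The shPHF19 libraries sit between 33.1 and 41.1 CPM for PHF19, below the control libraries at 168 to 199 CPM.

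Most of the measured transcriptome differed between the groups. Of 13014 genes tested, 7835 (60.2%) passed an adjusted p of 0.05 in the edgeR quasi-likelihood test, 3820 of them higher and 4015 lower in shPHF19 cells. A list with about this share of its members called is not set apart from other genes by that count. The genes that changed at least 2-fold were unevenly split, with 744 higher and 1415 lower (2159 in all). The 3 values of each group did not overlap for 8260 genes (63.5%, where chance gives 10%). The first principal component held 77.6% of the variance between libraries, and correlations of log2 CPM were 0.986 to 0.990 within groups and 0.940 to 0.949 between them. The scaling factors also differed by group, at 1.06 to 1.09 in control and 0.919 to 0.945 in shPHF19 libraries. Scaled by library totals only, 2590 genes were higher and 5624 lower, so the share of higher genes among the changed ones was 31.5% in place of 48.8%. The median log2 fold change of all genes was then -0.24 in place of -0.03.

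**Figure D2:**
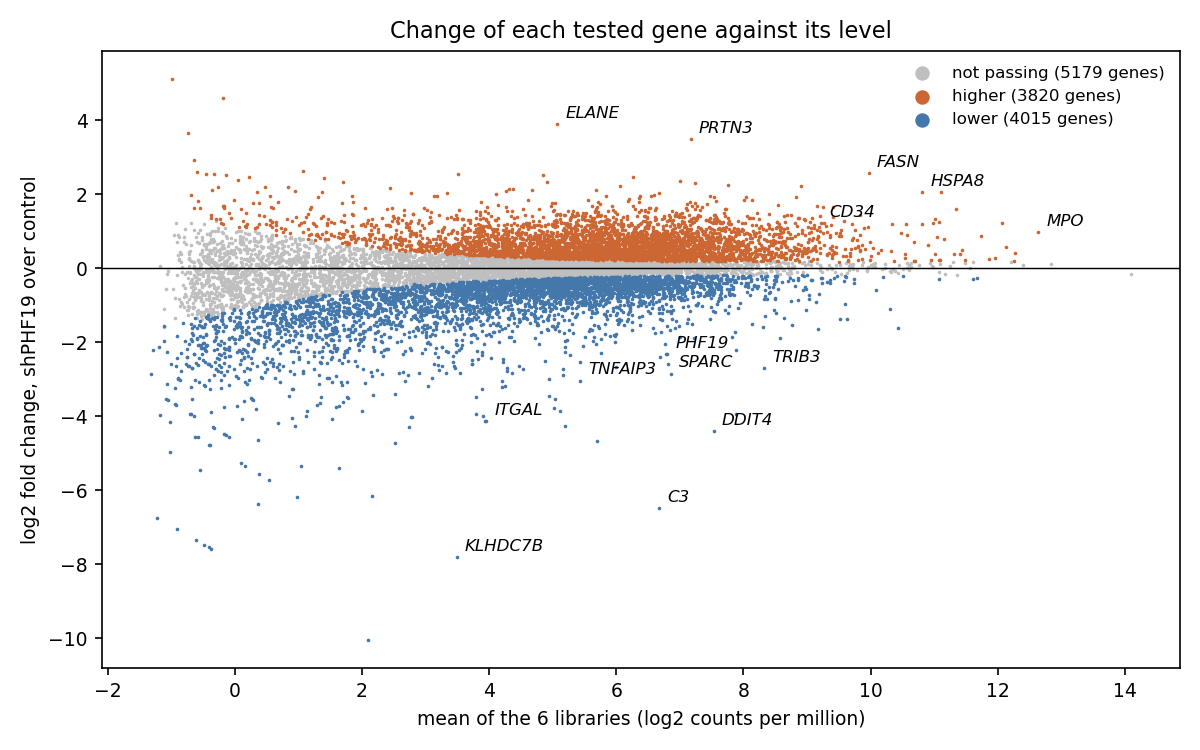
The log2 fold change of shPHF19 over control for each of 13014 tested genes against its mean level in log2 CPM, with 1 point per gene. Genes past the threshold are coloured (3820 higher, 4015 lower), and genes named in the text are labelled.

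Among genes with a mean of at least 5 CPM that met the naming rule, ELANE and PRTN3 rose most. Both are genes of the primary granules of neutrophil precursors. ELANE, which encodes neutrophil elastase, rose from 4.20 ± 1.33 to 63.2 ± 7.73 CPM (14.9-fold, log2 fold change 3.90 with SE 0.153), and PRTN3, which encodes proteinase 3, rose from 23.7 ± 2.12 to 264 ± 16.0 CPM (11.1-fold, 3.48 with SE 0.0976; SD, n = 3 throughout). AZU1 (azurocidin, 2.45) and BPI (bactericidal permeability-increasing protein, 2.52) rose as well. AZU1, PRTN3 and ELANE are neighbours on chromosome 19. MPO, which encodes myeloperoxidase, was among the 3 genes with the most counts, and its share of all counts was 0.459 ± 0.0269% in control and 0.781 ± 0.0502% in shPHF19 libraries (log2 fold change 0.97). Of 41 listed granulocyte markers, 22 passed the expression filter, and the result covers only those. Of these 22, 12 rose, 2 fell and 8 did not pass the test, and adjusted over the list alone 13 rose and 2 fell. The list was called higher (camera adjusted p = 0.000517; adjusted p = 0.087 with an estimated correlation). Other genes with the largest rises were HGF (hepatocyte growth factor, 2.35), CST7 (cystatin F, 2.33), EGFL7 (2.30), PRDX1 (peroxiredoxin 1, 2.25), ACTL8 (2.22) and CD247 (the CD3 zeta chain, 2.55).

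Most genes on the list of monocyte and macrophage markers moved the opposite way. The expression filter left 29 of 46 listed. Of these 29, 19 fell, 3 rose and 7 did not pass, with the same counts when adjusted over the list alone. The median log2 fold change was -1.53. ITGAM (CD11b) fell from a mean of 34.4 to 3.80 CPM (n = 3; -3.17 with SE 0.159) and ITGAX (CD11c) from 31.9 to 5.49 CPM (n = 3; -2.53 with SE 0.156). SERPINA1 (-1.51), the Fc receptor gene FCGR1A (-1.57) and the lysozyme gene LYZ (-1.53) also fell. The list was called lower (camera adjusted p = 0.000136; adjusted p = 0.087 with an estimated correlation). The leukocyte integrin ITGAL (-4.13), the galectin gene LGALS1 (-3.52) and the tetraspanin CD82 (-2.45) fell, while the integrin ITGA4 rose (1.37). These 4 belong to a list of 28 adhesion and migration genes that was not called as a set (14 lower, 7 higher, also when adjusted over the list alone; camera adjusted p = 0.369). CD34, a surface marker of haematopoietic progenitors, rose from 357 ± 11.2 to 830 ± 21.8 CPM (1.22). Among 34 stem and progenitor genes 10 rose, 8 fell and 16 did not pass, also when adjusted over the list alone, and the set was not called (camera adjusted p = 0.913).

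**Figure D3:**
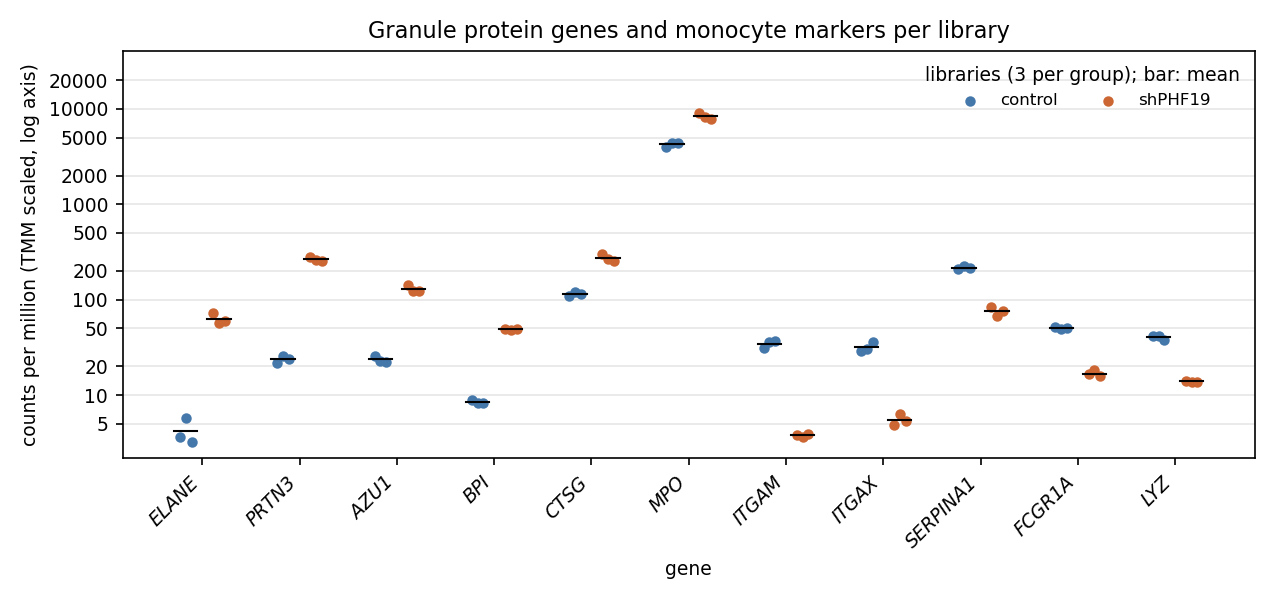
CPM of 6 granule protein genes (ELANE to MPO) and 5 monocyte and macrophage markers (ITGAM to LYZ) on a log axis, with 1 point per library (3 control, 3 shPHF19) and a bar at the mean of each group. For example, ELANE means are 4.20 and 63.2 CPM and ITGAM means are 34.4 and 3.80 CPM in control and shPHF19 libraries.

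Genes of the integrated stress response were lower in shPHF19 cells. DDIT4, an inhibitor of mTORC1 signalling, fell from 353 ± 20.4 to 16.7 ± 0.127 CPM (21.1-fold lower, log2 fold change -4.40), and TRIB3 fell from 554 ± 47.9 to 85.7 ± 9.63 CPM (-2.69; SD, n = 3). The transcription factor DDIT3 (CHOP, -2.68) and the phosphatase subunit PPP1R15A (GADD34, -2.40) fell too. Of 34 measured members of the integrated stress and amino acid response 28 fell, 1 rose and 5 did not pass, also when adjusted over the list alone (camera adjusted p = 1.89e-09; adjusted p = 0.064 with an estimated correlation).

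Inflammatory and immediate early genes were lower as well. Of 29 members of the NF-kappaB and inflammatory response 18 fell, 1 rose and 10 did not pass, also when adjusted over the list alone (camera adjusted p = 0.000142; adjusted p = 0.20 with an estimated correlation). TNFAIP3, a feedback inhibitor of the pathway, fell from 77.1 ± 5.33 to 9.40 ± 2.12 CPM (-3.04; SD, n = 3), and TRAF1 (-2.78), SAT1 (-1.62) and the interleukin-8 gene CXCL8 (-1.84) fell. Of 24 immediate early genes 15 fell, 3 rose and 6 did not pass, also when adjusted over the list alone, among them JUN (-1.36), ATF3 (-1.66), SGK1 (-1.89) and KLF2 (-2.09), each lower (camera adjusted p = 0.00624; adjusted p = 0.25 with an estimated correlation).

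Among single genes, the complement gene C3 fell from 201 ± 26.9 to 2.25 ± 0.237 CPM (88.8-fold lower, -6.47; SD, n = 3). KLHDC7B had 1083 counts in the control libraries together and 4 in the shPHF19 libraries, a ratio of 242 with an exact 95% counting interval of 94.1 to 889. INHBE (-4.72), TM6SF1 (-4.67), SETBP1 (-4.28), MFAP4 (-4.26), ANXA1 (annexin A1, -4.14), RGS3 (-4.03), GPR34 (-4.01) and IL20RB (-3.98) completed the 12 largest falls. The annotated spans of C3 and IL20RB overlap those of other counted genes (GPR108 and NCK1) on the same strand, and those of PRDX1, MFAP4 and GPR34 overlap counted genes on the opposite strand. Whether reads were counted by strand is not given in the sources used here, so the values of these 5 genes are less certain.

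Genes of lipid synthesis were higher in shPHF19 cells. All 32 measured genes of cholesterol and fatty acid synthesis rose, also when adjusted over the list alone, with a median log2 fold change of 1.14 (camera adjusted p = 2.46e-13; adjusted p = 0.064 with an estimated correlation). FASN, which encodes fatty acid synthase, rose from 289 ± 30.1 to 1712 ± 192 CPM (5.92-fold, 2.57), and the sterol pathway genes FDPS (1.96) and DHCR7 (1.92) rose.

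Growth-related genes rose with them. Of 48 measured MYC targets and ribosome biogenesis genes 40 rose and 8 did not pass, also when adjusted over the list alone, and the median log2 fold change was 0.88 (camera adjusted p = 2.46e-13; adjusted p = 0.064 with an estimated correlation). Examples were the prohibitin gene PHB (1.86), NME1 (1.94), the translation factor EIF5A (1.47) and the spermidine synthase gene SRM (1.56). Of 43 nuclear genes of oxidative phosphorylation 37 rose, 1 fell and 5 did not pass (38 rose and 1 fell when adjusted over the list alone), including COX6B1 (1.30), NDUFA4 (1.27), SDHA (1.20) and NDUFA9 (1.48). That list was called higher (camera adjusted p = 1.13e-09; adjusted p = 0.25 with an estimated correlation). Among 33 genes of glycolysis and hypoxia 16 rose, 11 fell and 6 did not pass, also when adjusted over the list alone, and the set was not called (camera adjusted p = 0.363). PKM (1.33), PFKP (1.37), PGK1 (1.19) and TPI1 (1.16), all glycolytic, were among those that rose.

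Most genes of the unfolded protein response and heat shock rose. Of 31 measured members of that list 25 rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 6.58e-06; adjusted p = 0.22 with an estimated correlation). HSPA8, a cytosolic chaperone of the HSP70 family, rose from 693 ± 13.7 to 2899 ± 145 CPM (2.07; SD, n = 3), and PDIA4 (1.83), DNAJA1 (1.81) and HSP90AA1 (1.40) rose. The 6 that fell, named after their values were seen, were HERPUD1 (-1.68) and SEL1L (-1.16), which act in degradation from the endoplasmic reticulum, the chaperones and co-chaperones DNAJB9 (-0.68), DNAJC3 (-0.48) and CANX (-0.34), and the transcription factor XBP1 (-0.20).

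Cell cycle genes were higher by smaller amounts. Of 54 genes of G2/M and mitosis 38 rose, 4 fell and 12 did not pass (39 rose and 4 fell when adjusted over the list alone; camera adjusted p = 5.17e-08; adjusted p = 0.14 with an estimated correlation). BIRC5 (survivin, 1.35), CCNB1 (cyclin B1, 1.40), TPX2 (1.05) and PLK1 (1.18) were the clearest. Of 49 genes of G1/S and DNA replication 34 rose, 8 fell and 7 did not pass (35 rose and 8 fell when adjusted over the list alone; camera adjusted p = 0.000136; adjusted p = 0.064 with an estimated correlation), including RRM2 (1.09), FEN1 (1.04), MCM7 (0.98) and POLD1 (1.04). The cyclin-dependent kinase inhibitor gene CDKN1A (p21) fell from 79.3 ± 4.42 to 20.4 ± 3.13 CPM (-1.96), and CDKN2C (p18) rose from 61.2 ± 2.33 to 166 ± 4.01 CPM (1.44; SD, n = 3). Among 30 p53 targets 15 fell, 6 rose and 9 did not pass, also when adjusted over the list alone, with TNFRSF10B (-1.73), SESN2 (-1.77) and BBC3 (PUMA, -2.83) among those that fell. The p53 list missed the threshold (camera adjusted p = 0.0566) and was called with the gene length trend removed (camera adjusted p = 0.0394; up to 0.0905 over the alternatives). It was also called with the length and GC trends removed (camera adjusted p = 0.04). Of 28 apoptosis regulators 13 fell, 7 rose and 8 did not pass (14 fell and 7 rose when adjusted over the list alone; camera adjusted p = 0.363), with BMF lower (-2.63) and BIK (1.67) and BID (0.80) higher.

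**Figure D4:**
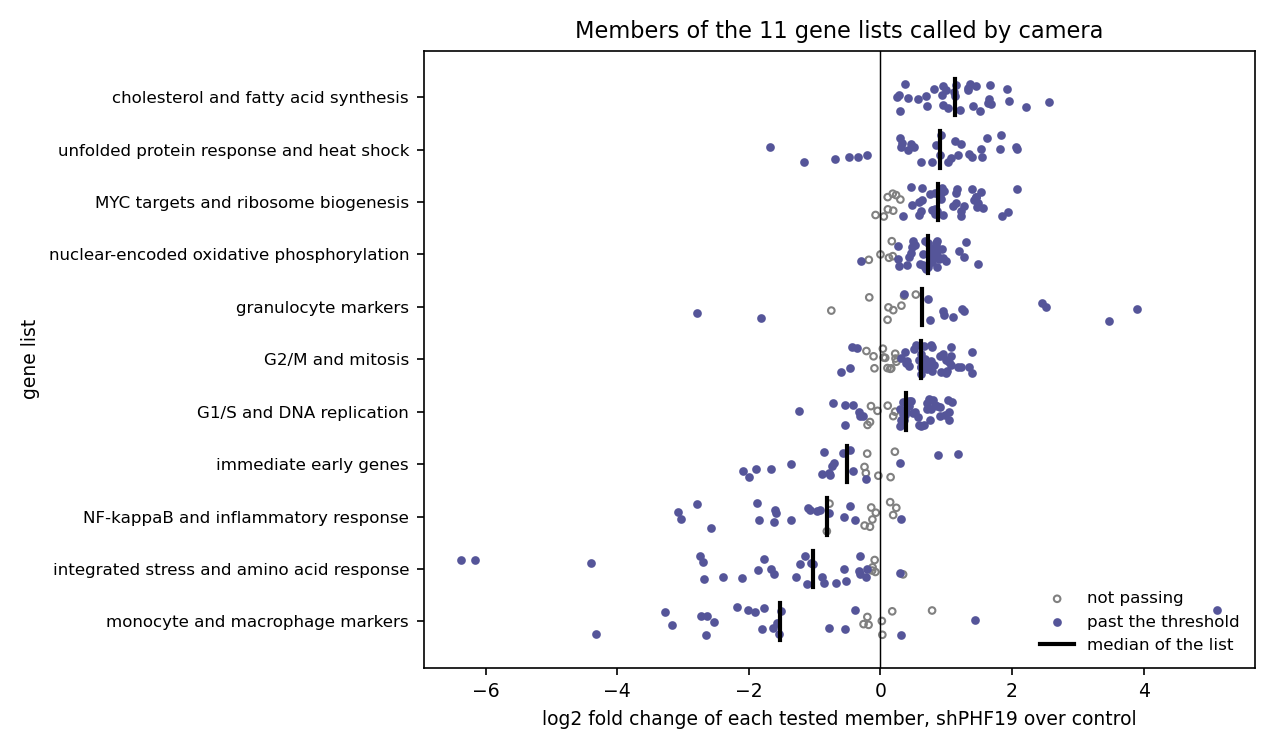
The log2 fold change of shPHF19 over control for each measured member of the 11 gene lists called by camera, with filled points past the edgeR threshold, open points not passing and a bar at the median of each list. Medians run from -1.53 for monocyte and macrophage markers to 1.14 for cholesterol and fatty acid synthesis.

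Among members that passed the expression filter, known classes of Polycomb targets were not called by camera, which compares a list with other genes. The filter left 29 of 80 listed developmental transcription factor genes and 9 of 38 listed HOX cluster genes. Most listed targets were therefore not tested, and the result covers only those with enough counts. Fry, which does not compare a list with other genes, called 24 of 35 lists. Among them were the developmental transcription factors (fry adjusted p = 0.0125), lower on average (mean log2 fold change -0.30). The HOX cluster genes (fry adjusted p = 0.0175) were higher on average (0.19). Fry also called the PRC1 subunits (adjusted p = 0.0159) and the histone H3 demethylase and methyltransferase genes (adjusted p = 0.0344), each lower on average (-0.22). Of 29 measured developmental transcription factor genes 4 rose, 11 fell and 14 did not pass, also when adjusted over the list alone (camera adjusted p = 0.465), with IRX3 (0.69) and DLX1 (0.46) higher and LHX2 (-1.49) lower. The HOX cluster genes had 9 measured members, of which 3 rose and 6 did not pass, also when adjusted over the list alone (camera adjusted p = 0.465). The log2 fold changes of HOXA11, HOXA10 and HOXA5 were 0.41, 0.60 and 0.51. With library totals only, none of the 3 was called (edgeR adjusted p = 0.17, 0.0797 and 0.119). With the length and GC trends removed, HOXA11 (0.18, limma-voom adjusted p = 0.139) and HOXA5 (0.33, limma-voom adjusted p = 0.069) were not called either. The call of HOXA10 was lost without control replicate 1 (0.47, edgeR adjusted p = 0.0517) or replicate 3 (0.50, edgeR adjusted p = 0.0509), and that of HOXA5 without control replicate 2 (0.39, edgeR adjusted p = 0.0622). Of 20 PRC1 subunits 4 rose, 7 fell and 9 did not pass, also when adjusted over the list alone (camera adjusted p = 0.45), with CBX6 (0.95) and CBX2 (0.55) higher and YAF2 (-1.04) lower. Among 18 demethylase and methyltransferase genes for histone H3 4 rose, 8 fell and 6 did not pass, also when adjusted over the list alone (camera adjusted p = 0.503). KDM6B (-1.44) and KDM6A (-0.67), which remove the mark that PRC2 places, both fell.

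Genes linked to the fusion in this line also went both ways. Of 14 genes that mark leukaemias with the fusion 4 rose, 7 fell and 3 did not pass (camera adjusted p = 0.70), and of 21 genes repressed by the fusion protein 7 rose, 9 fell and 5 did not pass (camera adjusted p = 0.913), each also when adjusted over the list alone. The second list shares ELANE, CTSG (1.27), MPO and LYZ with the myeloid marker lists. Markers of other lineages were not called by camera. The expression filter left 9 of 25 listed megakaryocyte and platelet markers, 9 of 29 erythroid and 14 of 39 lymphocyte markers. It left 11 of 24 mast cell, basophil and eosinophil markers and 11 of 32 fibroblast and epithelial markers. Of 9 megakaryocyte and platelet markers 1 rose and 3 fell, with SPARC lower (-2.84; camera adjusted p = 0.43). Of 9 erythroid markers 3 rose and 2 fell, with TFRC higher (1.36; camera adjusted p = 0.537). Of 14 lymphocyte markers 3 rose and 7 fell (camera adjusted p = 0.43), and of 11 mast cell, basophil and eosinophil markers 5 rose and 2 fell (camera adjusted p = 0.175). Of 11 fibroblast and epithelial markers 1 rose and 1 fell (camera adjusted p = 0.915). These 5 lineage lists had the same counts when adjusted over the list alone. Of 43 interferon-stimulated genes 9 rose and 18 fell, also when adjusted over the list alone (camera adjusted p = 0.295), with IFITM3 (1.24) higher and IRF7 (-1.93) lower. Of 22 antigen presentation genes 10 rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.735), with TAP2 (1.51) higher and CIITA (-1.82) lower. Of 72 cytosolic ribosomal protein genes 25 rose, 5 fell and 42 did not pass (23 rose and 4 fell when adjusted over the list alone; camera adjusted p = 0.0615). That list was called without control replicate 2 (camera adjusted p = 0.00354) or shPHF19 replicate 3 (camera adjusted p = 0.0185; 0.00354 to 0.78 over the alternatives). It was also called with no low-count filter (camera adjusted p = 0.00579).

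In all, camera with a preset correlation called 11 of 35 lists, 7 higher and 4 lower. With an estimated correlation camera called 0 lists (smallest adjusted p 0.064; 8 lists had an unadjusted p under 0.05), and fry called 24 (it is self-contained, so it does not compare a list with other genes). The authors' deposited table lists 5740 genes, 3043 with a log2 fold change above 0 and 2697 below 0. Of the genes in the authors' deposited table, 5732 were tested here, and each of them was called with the same sign. That table covers the same libraries and appears to hold only genes past stricter limits, so this match is no independent support. Its split into higher and lower is also not at the threshold used here. Of the genes called here, 2103 were absent from it, 747 of them with an edgeR adjusted p under 0.01 and a mean normalized count above 10.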

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

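The removal of a GC content trend, alone and with gene length, was chosen after the results were seen. The other alternatives were planned. Under the 18 alternatives that refit the genes, PHF19 stayed lower, with log2 fold changes of -2.53 to -2.24. The number of genes changed ranged from 7099 (without shPHF19 replicate 2) to 8214 (library totals only), against 7835, and of these calls 6605 (library totals only) to 7824 (without robust dispersion) were shared with the main set. Among shared calls, the sign was the same in each setting except for 1 gene with the length and GC trends removed (6728 of 6729). The genes changed at least 2-fold numbered 2007 to 2413, and a test against a 1.5-fold change called 2730. DESeq2 called 7648 genes and limma-voom 7854. Upper-quartile factors moved the median log2 fold change of all genes to -0.14 and called 3190 genes higher and 4778 lower. With no spike-in, the counts do not show which scaling reflects RNA per cell. Each of the 11 gene lists called by camera was called in the same direction in each of the 18 refits. The choice of set test mattered more: an estimated correlation called 0 lists and fry called 24, against 11. These tests differ by construction in how they treat correlation between genes and in what they compare a list with. Among values of named genes, 30 lost and 15 gained the threshold with the direction kept, and 2727 did neither. With the replicate number as a block, 7307 genes were called, 3555 higher and 3752 lower, and 11 lists. With the block and an estimated correlation, camera called 0 lists. The labels do not say that the numbers pair the libraries, and same-numbered libraries did not deviate together (correlations across genes -0.16, -0.0066 and -0.054), so the block is not read as a pairing. Depth limits the low genes: 3 counts correspond to about 0.2 CPM, and calls among genes near that level rest on few counts.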

Other observations

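The lists in the next paragraph, the neighbourhood of PHF19, the comparison with the control cells' state and the test of monocyte-like cells were chosen only after the results were seen. The GC part of the length and GC test and the FOXO list were also added after the main results. The idea of FOXO came from genes already seen to fall (BBC3, BMF and KLF2 among them), but the members tested were listed before their own values were seen. Genes named in this section and not in the report were chosen after their values were seen.

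Other parts of the protein production and quality control machinery were higher in shPHF19 cells. All 8 subunits of the cytosolic chaperonin rose, among them CCT3 (log2 fold change 1.44) and CCT5 (1.27; camera adjusted p = 0.00018 over 9 added lists; adjusted p = 0.13 with an estimated correlation). Of 37 proteasome subunit genes 29 rose and 8 did not pass, with PSMB3 (1.43) and PSMD3 (1.42) among the highest (camera adjusted p = 3.06e-09; adjusted p = 0.13 with an estimated correlation). Of 76 mitochondrial ribosomal protein genes 56 rose, among them MRPL12 (1.27), 4 fell and 16 did not pass (camera adjusted p = 1.62e-09; adjusted p = 0.13 with an estimated correlation). Of 44 genes with EIF symbols, a list that holds translation initiation factors but also the kinases EIF2AK1 to EIF2AK4 and repressors such as EIF4EBP1, 21 rose, 6 fell and 17 did not pass. The subunit gene EIF3B was higher (1.26), as was the kinase gene EIF2AK1 (0.83; camera adjusted p of the list 0.0059; adjusted p = 0.13 with an estimated correlation), and the median of the list turned from 0.19 to -0.01 with library totals only. Genes with ZNF symbols, which encode zinc finger proteins, went down more often than up. Of 386 measured, 158 fell, 38 rose and 190 did not pass, with ZNF467 (-1.40) and ZNF469 (-2.80) lower (camera adjusted p = 0.00048; adjusted p = 0.13 with an estimated correlation). The Toll-like receptor genes TLR1 (-2.60) and TLR6 (-2.82) fell, but the list of 13 receptors and adaptors did not pass (camera adjusted p = 0.0519), though it was called in 10 of 18 alternatives (adjusted p up to 0.087). Genes of autophagy and lysosomes went both ways, with 12 higher, 13 lower and 8 not passing (camera adjusted p = 0.605), and so did solute carriers, with 59 higher, 55 lower and 78 not passing (camera adjusted p = 0.605). With an estimated correlation none of the added lists passed (smallest adjusted p = 0.13).

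In the 10 splits of the 6 libraries into 3 and 3, the real one gave 7835 genes changed, 3820 higher, 4015 lower and 2159 at least 2-fold, and in each of these counts only 1 split, the real one, reached the real value. In the other 9 splits edgeR called 0 genes, with at most 164 at an unadjusted p under 0.05. For gene lists, 4 of the 10 splits gave as many as the real 11, and the highest of the others gave 13. With 10 splits no share can fall under 0.05. Each of the other 9 splits has control and shPHF19 libraries on both sides. The difference between the groups then adds to the spread within the sides, so 0 genes called there follows from the design. Those sides still differ in how many shPHF19 libraries they hold, so their list counts keep part of that difference. For neither count do the splits measure chance.

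The first pattern is that lists of growth and synthesis were higher and the integrated stress list lower. Gene length and GC content argue little for it: after both trends were removed in limma-voom, the smallest ratio of corrected to uncorrected median over the 11 called lists was 0.743 (granulocyte markers), and each list was still called. What stays open is the state of the cultures. The stress list's mean log2 CPM in the lowest control library was 1.24 above that of the highest shPHF19 library, against a widest range within a group of 0.0812, and a difference in density or medium between control and shPHF19 wells may give such a gap as well as the hairpin, so these cannot be told apart where each group has its own cultures and the labels do not say how the replicates were grown. A hypothesis of lower FOXO transcription factor activity in shPHF19 cells was tested on 20 measured FOXO targets outside the fixed lists, of which 13 fell, 2 rose and 5 did not pass, with TXNIP (-1.38), PIK3IP1 (-1.87) and CCNG2 (-1.80) lower (camera p = 0.000293; adjusted p = 0.13 with an estimated correlation), which is consistent with it but does not separate it from the state of the cultures.

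The second pattern is that 19 of 29 measured monocyte and macrophage markers were lower while granule genes were higher. Fewer monocyte-like cells in the shPHF19 cultures may account for the falls, and bulk counts cannot tell this apart from lower transcription in each cell. The list was not checked for genes that other myeloid cells also express, so the falls are not assigned to 1 lineage. Of the same markers 10.3% rose, a share that restates the falls and so tests neither reading. Those that rose were CTSS (0.31), MNDA (1.43) and FCN1, which had 1 count in the control and 43 in the shPHF19 libraries (ratio 48.2, exact counting interval 8.2 to 1950). Both readings leave open whether the hairpin against PHF19 or another property of the cultures was responsible.

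The third pattern concerns genes beside PHF19. TRAF1, 7497 bp away, fell (-2.78), as did C5 (-1.52), while PSMD5, 12668 bp away on the other side, had a log2 fold change of 0.01 (SE 0.101). The 6 measured genes within 200 kb of PHF19 had a median log2 fold change of -0.60, and 5.07% of 7552 neighbourhoods of other genes were as low, as were 11% of the neighbourhoods of 200 other genes that fell at least 4-fold. A local effect around PHF19 may exist but cannot be told apart from chance clustering of lower genes, and TRAF1 is also a member of the NF-kappaB list that was lower. A second hairpin was not analysed here, so effects of the hairpin on other transcripts were not tested.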
